A study of Mus musculus with 6 samples.

How the data were processed

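Total RNA was extracted with Trizol, labelled with biotin and hybridised to single-colour expression arrays, per the labels' protocols. The 6 arrays hold 3 samples with a non-targeting guide (control) and 3 with a guide against Cbfb (knockout), and groups and replicate numbers were taken from the sample labels. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

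The deposited table holds log2 expression values, and the submitters' processing notes name RMA and limma 3.14.4 without a role or order for either. RMA corrects background, quantile-normalises arrays and summarises probes on a log2 scale. That scale was read from the values, which lie between 0.66 and 12.51, and it was not stated in the labels. Quantile normalisation gives arrays nearly the same distribution, so a change shared by most genes would not be seen. The values carry no detection calls, and RMA compresses differences near background, so changes of genes at low values are understated. Signals near the top of the range can saturate, which the values do not show. The table has 25206 rows, of which 23185 have 1 gene symbol, 0 have several and 2021 have none. All 23185 symbols were matched through the Entrez number to a RefSeq gene table of assembly GRCm38.p6, used for names only, and no coordinates are printed because the sources used here give no build for the array.

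The values were used as deposited, with no filter and no further normalisation. The main test was limma 3.58.1 in R 4.3.3, with 1 coefficient per group, the contrast knockout minus control, and moderated two-sided tests with the default prior (4.1 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg over all 25206 rows, with a threshold of 0.05 on the adjusted p. The median residual SD of a row was 0.131 on the log2 scale. Lists were tested with camera from limma, with a preset inter-gene correlation of 0.01 and adjustment over 28 lists. The 28 lists hold 584 entries, of which 550 had a named row (4 through an older symbol), with 10 to 31 genes measured per list. Some genes stand in more than 1 list, so the lists are not independent of each other.

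The named genes followed a rule set before the data were examined, as were the lists, the tests and the alternatives except where stated. Named were Cbfb and the RUNX genes, a panel of ILC2 genes whatever their result, and the 12 largest rises and 12 largest falls among rows past the threshold. These rises and falls also needed no overlap between the groups' arrays, a higher group mean above 3.6 (the median of all group means) and 1 symbol of an established gene. Added were up to 4 members of each list with the smallest adjusted p. Of the target and panel genes 5 had no named row and were not analysed here.

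The alternatives were the replicate number as a block, leaving out each array in turn, quantile normalisation of the 6 columns again, centring of each column, and rows above the median level alone. Others were a trended and robust prior, array weights, an ordinary test without moderation, other thresholds, named rows alone, camera with an estimated correlation or on ranks, and fry. The gene test was checked on simulated data of the same shape for the comparison of knockout with control, with 25206 rows. Of 67 rows changed by 0.5 on the log2 scale 34.3% were recovered, of 67 changed by 1 80.6%, and of 66 changed by 2 93.9%, with 7 false calls among 146. In simulated lists 1 list had every member lowered by 0.5 on the log2 scale. It was called, and 0 of 27 unshifted lists were. That shift exceeds the median change of every list called below except immediate early genes. It therefore does not show how often smaller or mixed shifts are found. Simulated rows varied independently of each other, so this check cannot show how camera behaves where members of a list vary together.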

Results

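Group 2 innate lymphoid cells (ILC2s) are lymphocytes without antigen receptors that answer IL-33 by making type 2 cytokines. Expression was measured in mouse ILC2 lines of the C57BL/6J strain, cultured with IL-2 and IL-33 at 10 ng/ml. The cells carried a lentiviral CRISPR construct with either a guide against Cbfb or a guide without a target, and GFP-positive cells were sorted 6 days after transduction. Each guide had 3 arrays, called control and knockout here, and 6 arrays gave values for 25206 rows, 1 per Entrez gene. Values are on a log2 scale, and their medians per array lay between 3.57 and 3.63. No pair of arrays was identical, Pearson correlations across rows were 0.9946 to 0.996 within groups, and they were 0.988 to 0.9908 between groups. Across genes, the first principal component held 52% of the variance. It placed the control arrays at -24.1 to -21 and the knockout arrays at 19.4 to 25.9. The number of arrays limits the precision.

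The comparison asks what loss of core-binding factor beta, the partner that stabilises RUNX proteins on DNA, does to gene expression in stimulated ILC2s. The targeted gene itself, Cbfb (Entrez gene 12400), read 8.53, 8.73 and 8.70 in the control arrays and 7.88, 7.69 and 7.91 in the knockout arrays. Its mean fell from 8.65 ± 0.11 to 7.83 ± 0.12 (SD, n = 3 arrays per group), a change of -0.83 with a standard error of 0.099 (limma adjusted p = 0.00205). On a linear scale 56.4% of the control signal remained (95% interval 48.2% to 66%). A CRISPR deletion or insertion need not remove the transcript, so the array value measures neither the edit nor the protein. Runx1, which encodes a DNA-binding partner of CBFβ, rose from 6.78 ± 0.22 to 8.05 ± 0.18 (2.42-fold, limma adjusted p = 0.00121). Runx3, which encodes another partner, read 9.06 ± 0.17 and 9.30 ± 0.042, a difference of 0.24 that did not pass the test (adjusted p = 0.198). Of 10 measured core-binding factors and corepressors, Runx1 rose, Cbfb fell and 8 did not pass, the same counts as when adjusted over the list alone. The list had a median of 0.18 and was not called by camera (adjusted p = 0.394). Among its corepressors, Tle4 differed by 0.40 (limma adjusted p = 0.104) and Tle1 by -0.36 (limma adjusted p = 0.161). Tle4 read 3.10 and 3.50 and Tle1 2.27 and 1.92 in control and knockout, low values where changes can be understated.

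**Figure D1:**
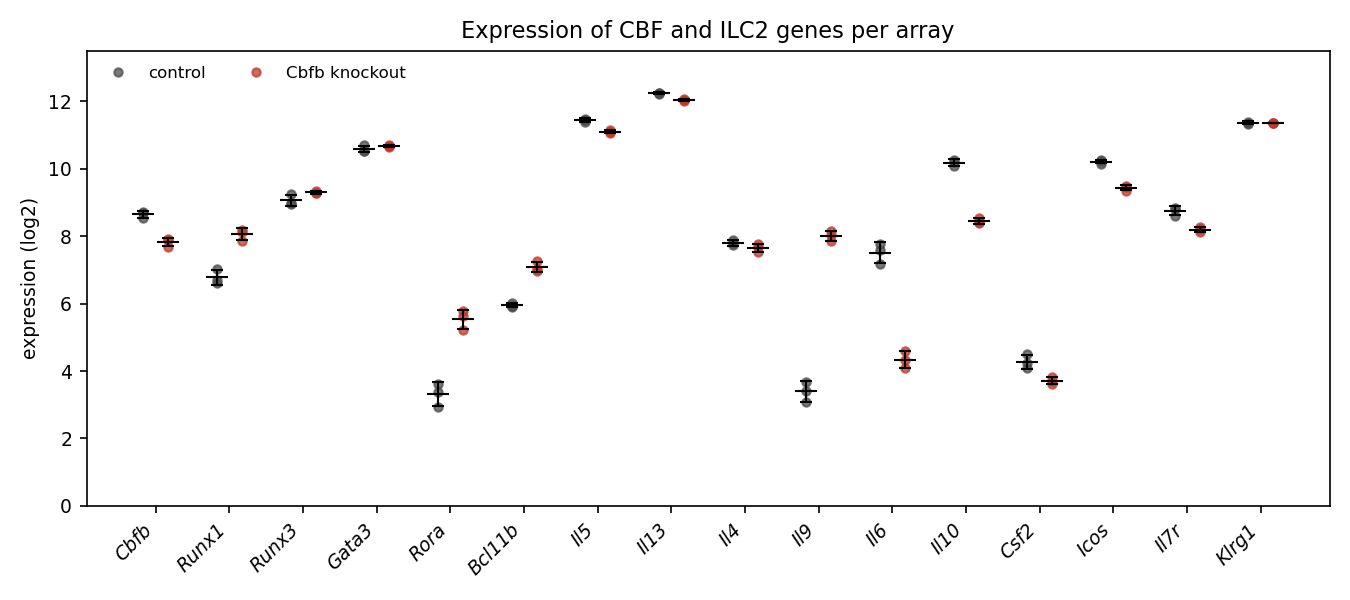
Log2 expression of 16 genes of the core-binding factor and of ILC2s on each array, with control arrays in grey and knockout arrays in red; black bars give the mean and SD of 3 arrays. Il9 stands at 3.39 in control and 8.01 in knockout, Il6 at 7.51 and 4.34, and Gata3 at 10.58 and 10.68.

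The largest measured rise was that of Il9, the gene of a type 2 cytokine that acts on ILC2s and mast cells. It went from 3.39 ± 0.30 to 8.01 ± 0.15, or 24.5-fold as measured (SD, n = 3; limma adjusted p = 1.8e-05). Its control mean lies under 3.6, the median of all group means, as do those of Rora and Fabp4 and the knockout mean of Nr4a3. No detection calls tell signal from background there, so the folds and ranks of these 4 genes are approximate and their changes can be understated. The value 3.6 is no detection limit, and the same caution holds for genes just above it. Among the named rises and falls these are the control means of Hey1 (3.85), Pde7b (3.88), Gpnmb (3.89) and Blnk (3.93) and the knockout mean of Cpa3 (3.96). Il6, which encodes an inflammatory cytokine, had the largest fall under the rule for named genes, from 7.51 ± 0.31 to 4.34 ± 0.25 (8.98-fold lower, adjusted p = 9.21e-05). In all, 2457 of the 25206 rows changed, 9.75% of those tested. Of these 1389 were higher and 1068 lower in the knockout, with 161 higher and 119 lower by at least 1 on the log2 scale. The arrays of the groups did not overlap in any of the 2457 rows. Over all rows 6940, or 27.5%, had no overlap, where chance gives 10% for 3 against 3, and 5780 had an unadjusted p under 0.05.

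Among the 12 largest named rises, Pde7b, a cyclic AMP phosphodiesterase gene, followed Il9. It went from 3.88 ± 0.11 to 7.98 ± 0.17 (17.2-fold, limma adjusted p = 6.35e-06). Gpnmb, which encodes a transmembrane glycoprotein of endosomes and lysosomes, rose 9.11-fold from 3.89 ± 0.14 to 7.07 ± 0.25. Grn, the gene of the secreted growth factor and lysosomal protein progranulin, rose 3.94-fold from 8.19 ± 0.15 to 10.16 ± 0.16. Ccl24, the gene of an eosinophil-attracting chemokine, rose 4.49-fold, and Fabp4, a carrier of fatty acids, 5.18-fold. The orphan nuclear receptor gene Rora, which ILC2s need for their development, rose 4.65-fold from 3.32 ± 0.35 to 5.53 ± 0.29. Tnfrsf23, a decoy receptor for TRAIL, rose by 2.81 on the log2 scale, the imprinted zinc finger gene Peg3 by 2.12, and Ttc39a rose 3.99-fold. Blnk, which encodes an adaptor protein of B cell receptor signalling, rose by 2.10, and Hey1, a transcriptional repressor that Notch can induce, by 1.88. Adjusted p lay between 6.35e-06 and 0.000834 (limma) across the 12.

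After Il6, the largest named falls were those of Cpa3 and Nr4a3. Cpa3, which encodes a carboxypeptidase best known from mast cells, fell 7.53-fold from 6.87 ± 0.26 to 3.96 ± 0.14. The orphan nuclear receptor gene Nr4a3 fell 7.33-fold from 5.47 ± 0.17 to 2.59 ± 0.24. Rel, the gene of the NF-κB subunit c-Rel, fell 6.32-fold from 9.28 ± 0.34 to 6.62 ± 0.29. Nlrp3, which encodes an inflammasome sensor, fell 5.52-fold from 7.13 ± 0.15 to 4.67 ± 0.18. Ctla4, the gene of an inhibitory receptor of lymphocytes, fell 4.38-fold from 9.0 ± 0.17 to 6.87 ± 0.23. Il24, a cytokine gene of the IL-10 family, went from 9.07 ± 0.23 to 6.78 ± 0.35. The granzyme gene Gzmc fell by 2.39 on the log2 scale, and the metalloprotease gene Adamts1 fell by 2.30. Lipo1, a lipase family gene, fell by 2.83, the keratin gene Krt23 fell by 2.19, and the inhibitory receptor gene Cd300a fell by 2.09. Adjusted p lay between 6.19e-05 and 0.000641 (limma) for these 12 falls. Gzmc, Lipo1 and Tnfrsf23 have close relatives in their gene families, whose transcripts the values alone do not separate. Without control replicate 2 the count of changed genes was 1307, without control replicate 3 1565, without knockout replicate 2 1478 and without knockout replicate 3 1517.

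**Figure D2:**
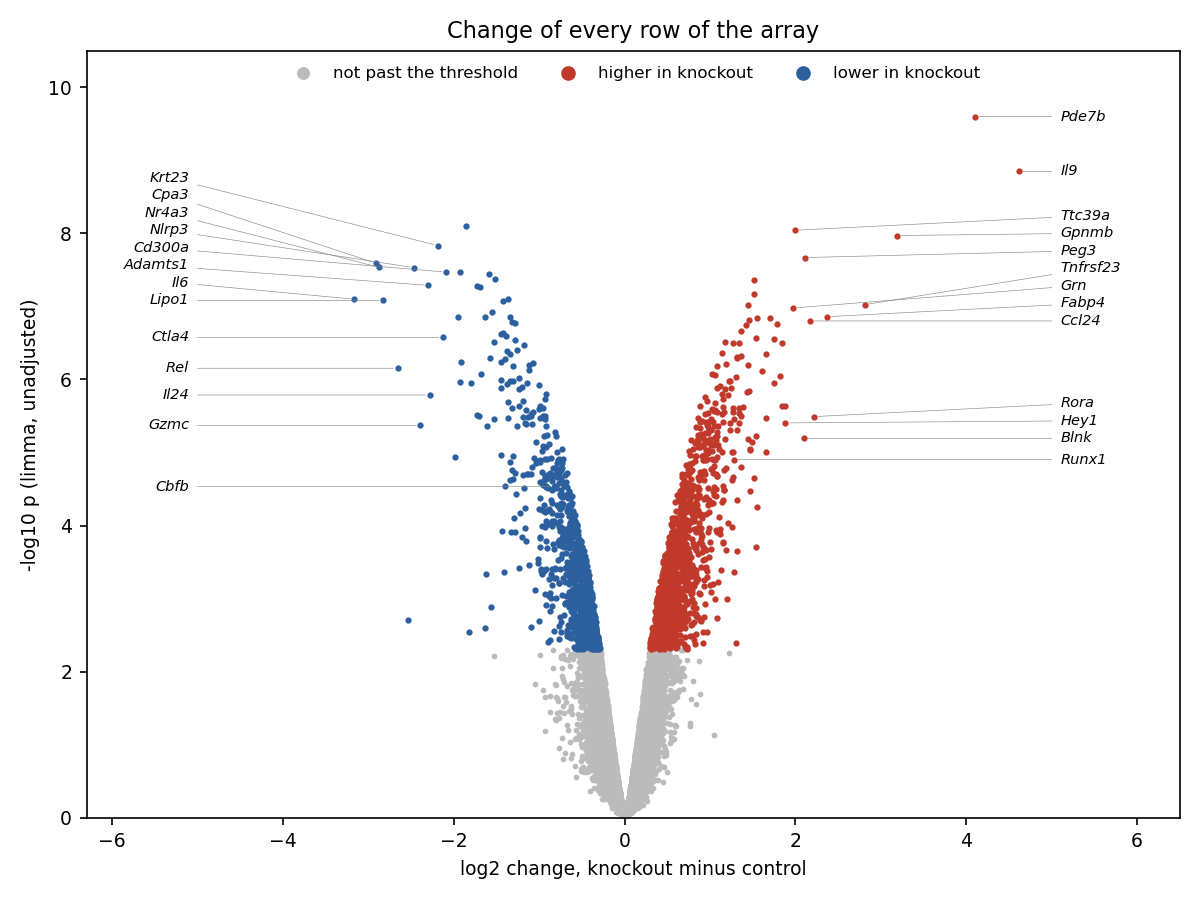
Log2 change (knockout minus control) of each of the 25206 rows against the negative log10 of its unadjusted limma p; red and blue points are the 1389 higher and 1068 lower genes with an adjusted p under 0.05. The named rises and falls, Cbfb and Runx1 carry labels, with Il9 at 4.61 and Il6 at -3.17 as the outermost labelled points.

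Among the type 2 cytokines, Il5, which drives eosinophils, fell from 11.44 ± 0.055 to 11.10 ± 0.035 (1.26-fold, limma adjusted p = 0.0349). Il13, which drives mucus production and airway reactivity, read 12.25 ± 0.015 and 12.04 ± 0.031, a difference of -0.20 that did not pass (adjusted p = 0.149) but passed in 3 of 13 alternatives (adjusted p 0.00143 to 0.313 over the 13). Il5 and Il13 read near the highest value on an array, 12.43 to 12.51, where signals can saturate and differences can be understated. Il4 read 7.80 ± 0.081 and 7.66 ± 0.12 (adjusted p = 0.428). Il10, the gene of an anti-inflammatory cytokine, fell 3.32-fold from 10.18 ± 0.095 to 8.45 ± 0.089 (adjusted p = 7.54e-05). Csf2, which encodes GM-CSF, fell from 4.28 ± 0.21 to 3.71 ± 0.10 (adjusted p = 0.0214), and Lif, a cytokine gene of the IL-6 family, fell by 0.47 on the log2 scale. Arg1, an arginine-metabolising enzyme of ILC2s, read 9.50 ± 0.17 and 9.47 ± 0.046 (95% interval of the difference -0.27 to 0.20). Of 14 measured type 2 effector products, 6 fell, 2 rose and 6 did not pass. Adjusted over the list alone, 8 fell and 3 rose. The list was called lower by camera, with a median of -0.27 (adjusted p = 0.0105; adjusted p = 0.165 with an estimated correlation). Il5 missed the threshold in each of the 6 fits that left out 1 array (adjusted p 0.0701 to 0.116), and Csf2 missed it in 4 of them (adjusted p 0.0234 to 0.0771 over the 6).

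Factors and receptors that mark ILC2s moved in both directions. Bcl11b, a transcription factor gene that maintains ILC2 identity, rose from 5.95 ± 0.068 to 7.09 ± 0.15 (limma adjusted p = 0.000549). Maf, a transcription factor gene tied to IL-10 and type 2 cytokine expression, rose from 9.02 ± 0.046 to 9.96 ± 0.021 (adjusted p = 0.000415). Icos, a costimulatory receptor gene, fell from 10.21 ± 0.053 to 9.43 ± 0.074 (adjusted p = 0.00121), and Il7r, the receptor chain for IL-7 and TSLP, fell from 8.76 ± 0.13 to 8.20 ± 0.075 (adjusted p = 0.00966). Gata3, the lineage-defining transcription factor gene of ILC2s, read 10.58 ± 0.095 and 10.68 ± 0.026 (95% interval of the difference -0.094 to 0.29; adjusted p = 0.566). Klrg1, an inhibitory receptor of mature ILC2s, read 11.37 ± 0.035 and 11.36 ± 0.010 (interval -0.18 to 0.17). Il2ra, the IL-2 receptor alpha chain, differed by -0.23 (adjusted p = 0.132). The surface marker Thy1 differed by 0.01 (adjusted p = 0.979) and Zbtb16, the gene of the precursor-stage factor PLZF, by 0.07 (adjusted p = 0.746). Thy1 read 3.41 and 3.41 and Zbtb16 3.29 and 3.36 in control and knockout, under 3.6, the median of all group means. A change of either could therefore be understated. Of 24 measured ILC2 identity factors and receptors, 4 rose, 8 fell and 12 did not pass. Adjusted over the list alone, 5 rose and 12 fell. Camera did not call the list (median -0.13, adjusted p = 0.176).

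Immediate early genes, which are transcribed within minutes of receptor signalling, moved furthest as a list. Of 20 measured, 13 fell, none rose and 7 did not pass. Adjusted over the list alone, 15 fell and 1 rose. Besides Nr4a3, its relative Nr4a1 fell from 7.95 ± 0.30 to 6.03 ± 0.12, Ier3 from 9.86 ± 0.10 to 7.93 ± 0.11, and the AP-1 member Fosl2 from 9.21 ± 0.21 to 7.89 ± 0.026. The median change was -0.82 (camera adjusted p = 6.63e-13; adjusted p = 0.162 with an estimated correlation). In the IL-33 receptor and NF-kB pathway 9 of 21 measured genes fell and none rose (adjusted over the list alone, 11 fell and 2 rose). Its examples besides Rel are Tnfaip3, which encodes the feedback inhibitor A20, with a change of -1.15 (limma adjusted p = 0.000616), Nfkbiz, an atypical IκB gene, with -0.81 and the kinase gene Map3k8 with -0.66. This list had a median of -0.28 and a camera adjusted p of 2.56e-05 (adjusted p = 0.162 with an estimated correlation). Some of these 9 genes encode inhibitors of NF-κB, as A20 does, and others its subunits, as c-Rel.

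IL-2 and STAT5 response genes were lower in 10 of 18 measured members and higher in 2 (adjusted over the list alone, 13 and 2). The kinase gene Pim2 fell from 9.31 ± 0.025 to 7.93 ± 0.14 (limma adjusted p = 0.000187). Osm, the oncostatin M gene, fell by 0.74 on the log2 scale and Stat5a, a transducer of IL-2 signals, fell by 0.69. The list was called lower with a median of -0.37 (camera adjusted p = 1.66e-05; adjusted p = 0.131 with an estimated correlation). Coinhibitory and exhaustion-associated genes fell in 8 of 20 measured members and rose in 2, which became 10 and 5 when adjusted over the list alone. Nr4a3, Ctla4, Nr4a1 and Il10 led the falls, and Maf was among the rises. Pdcd1, which encodes PD-1, read 4.64 ± 0.38 and 3.92 ± 0.23 and did not pass (adjusted p = 0.0561), although it passed in 3 of 13 alternatives (adjusted p 0.0246 to 0.234 over the 13), among them the fit without control replicate 3. The list median was -0.31 (camera adjusted p = 0.00183; adjusted p = 0.144 with an estimated correlation), and camera on ranks did not call this list (adjusted p = 0.119).

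Of 26 measured markers of type 1 lymphocytes and NK cells, 10 fell and 1 rose (adjusted over the list alone, 12 and 1). Gzmc, the cytotoxic granule gene Nkg7 (5.48 ± 0.079 to 3.95 ± 0.15, limma adjusted p = 0.000155), the NK receptor gene Klrc1 (5.18 ± 0.28 to 3.86 ± 0.13) and Tnfsf10, which encodes TRAIL (8.62 ± 0.046 to 7.89 ± 0.064), all fell. The list median was -0.24 (camera adjusted p = 6.72e-05; adjusted p = 0.131 with an estimated correlation). Tbx21, the type 1 master regulator gene, differed by -0.15 (limma adjusted p = 0.574) and Ifng, its signature cytokine, by -0.15 (limma adjusted p = 0.464). Tbx21 read 3.59 and 3.45 and Ifng 2.63 and 2.47 in control and knockout, low values where changes can be understated. Type 3 lymphocyte markers had 2 rises and 1 fall among 12 measured (2 and 2 adjusted over the list alone; median -0.023, camera adjusted p = 0.793). The IL-1 receptor gene Il1r1 (0.52) and the lymphotoxin gene Ltb (0.47) rose, and Ahr, a ligand-activated transcription factor gene, fell by 0.52 on the log2 scale. Ltb missed the threshold in 5 of the 6 fits that left out 1 array, and Il1r1 in 1. Il1r1 read 2.24 and 2.76 in control and knockout, under 3.6, so its rise is approximate. Batf, an AP-1 family gene, differed by -0.29 (adjusted p = 0.0834).

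Markers of cell types other than innate lymphocytes mostly did not pass the test. Among 18 T cell markers Zap70, a proximal signalling kinase gene, rose by 0.33 on the log2 scale, while Trac, the T cell receptor alpha constant gene, fell by 0.61 and the signalling chain gene Cd247 fell by 0.50 (1 up and 4 down adjusted over the list alone; median -0.047, camera adjusted p = 0.43). The adaptor gene Lat differed by -0.46 (limma adjusted p = 0.069) and Cd4 by 0.21 (adjusted p = 0.266). Blnk rose alone among 14 B cell and antigen presentation markers, also when adjusted over the list alone (median 0.013, camera adjusted p = 0.793). Itgax, which encodes the integrin CD11c, fell from 5.81 ± 0.12 to 4.77 ± 0.17 and was the 1 gene past the test among 17 macrophage, monocyte and dendritic cell markers, by either adjustment, over all rows or adjusted over the list alone (median -0.033, camera adjusted p = 0.561). Of 13 mast cell and basophil markers Cpa3 fell, and the histamine-forming enzyme gene Hdc rose from 3.93 ± 0.13 to 5.39 ± 0.18. The transcription factor gene Gata2 rose from 4.62 ± 0.40 to 5.38 ± 0.13, and the IgE receptor gene Fcer1a differed by -0.17 (adjusted p = 0.359). Counts were the same adjusted over the list alone, and the list's median was 0.017 with a mean of -0.083 and a downward camera test (adjusted p = 0.866). Among 14 stromal, epithelial and endothelial markers the matrix gene Dcn rose by 0.65 and Pecam1, which leukocytes express too, fell by 0.31 on the log2 scale (the same counts adjusted over the list alone; median -0.048, camera adjusted p = 0.793). Kdr differed by -0.22 and Pdgfrb by 0.23, and neither passed. Cd4 (2.36 and 2.57 in control and knockout), Fcer1a (3.49 and 3.32) and Pdgfrb (2.58 and 2.81) read under 3.6, where changes can be understated. Zap70 and Pecam1 missed the threshold in all 6 fits that left out 1 array, Gata2 in 5 of them, Dcn in 4 and Cd247 in 1.

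Ribosome biogenesis and MYC response genes fell in 6 of 19 measured members, 9 adjusted over the list alone, and none rose. Nop58 fell from 9.22 ± 0.068 to 8.72 ± 0.059 (limma adjusted p = 0.00895), and the nucleolar genes Fbl (-0.50), Rrs1 (-0.46) and Wdr43 (-0.43) fell as well. The list median was -0.28 (camera adjusted p = 6.72e-05; adjusted p = 0.337 with an estimated correlation). S phase genes fell in 4 of 25, 7 adjusted over the list alone, and none rose. These were the ribonucleotide reductase gene Rrm2 (-0.47), the histone chaperone gene Chaf1b (-0.44), the E2F family gene E2f8 (-0.41) and the thymidylate synthase gene Tyms (-0.31). The S phase list had a median of -0.22 (camera adjusted p = 0.000329, and adjusted p = 0.521 with an estimated correlation). Its fall was uneven between arrays. Relative to the control mean, its members averaged -0.287, -0.158 and -0.0788 in knockout replicates 1, 2 and 3. Control replicates 1, 2 and 3 gave 0.0552, -0.0112 and -0.044. Without knockout replicate 1 the camera adjusted p was 0.0152. G2 and M phase genes were not called, with a median of -0.057, a mean of 0.0027 and a downward camera test (adjusted p = 0.833). Of 25 measured, the mitotic genes Anln (0.51), Plk1 (0.34) and Ttk (0.32) rose and none fell, with the same counts adjusted over the list alone, and Cdk1 differed by -0.25 (adjusted p = 0.115). Tyms and Ttk missed the threshold in all 6 fits that left out 1 array, Rrm2, E2f8, Fbl, Anln and Plk1 in 5 of them, Rrs1 and Chaf1b in 4, and Wdr43 in 1.

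In glycolysis 6 of 17 measured genes fell, by either adjustment, over all rows or adjusted over the list alone. The hexokinase gene Hk2 fell from 7.23 ± 0.17 to 5.86 ± 0.13 (limma adjusted p = 0.000472), the lactate exporter gene Slc16a3 from 8.17 ± 0.25 to 6.99 ± 0.17, the glucose transporter gene Slc2a3 from 9.93 ± 0.17 to 9.44 ± 0.090 and the phosphofructokinase gene Pfkp from 10.25 ± 0.11 to 9.83 ± 0.025. Slc2a3 and Pfkp missed the threshold in 5 of the 6 fits that left out 1 array. The list median was -0.19 (camera adjusted p = 0.000705; adjusted p = 0.46 with an estimated correlation). None of 24 oxidative phosphorylation genes passed, also adjusted over the list alone (median -0.12, camera adjusted p = 0.0547). That list was called lower without control replicate 1 (camera adjusted p = 0.00572) and without knockout replicate 3 (camera adjusted p = 0.0287), with array weights (adjusted p = 0.018) and by camera on ranks (adjusted p = 0.0393). Cholesterol synthesis genes fell in 6 of 17 and rose in 1 (7 and 2 adjusted over the list alone; median -0.27, camera adjusted p = 0.000996; adjusted p = 0.352 with an estimated correlation). Cyp51 changed by -0.86, the regulator gene Insig1 by -0.85 and the cyclase gene Lss by -0.75, while the reductase gene Hsd17b7 rose from 9.32 ± 0.14 to 10.34 ± 0.14. Genes of fatty acid uptake, storage and oxidation split, with 5 of 22 up and 4 down (7 and 7 adjusted over the list alone; median 0.0033, camera adjusted p = 0.866). The carrier genes Fabp4 (2.37) and Fabp5 (1.17) rose. Dgat1, which completes triglyceride synthesis, fell from 10.31 ± 0.17 to 8.36 ± 0.14, and the desaturase gene Scd1 from 7.45 ± 0.14 to 6.18 ± 0.31.

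Unfolded protein and amino acid stress response genes fell in 4 of 19, with 7 adjusted over the list alone and none up. These were the stress transcription factor genes Atf3 (6.02 ± 0.055 to 4.76 ± 0.22, limma adjusted p = 0.000643) and Atf4 (-0.47), the asparagine synthetase gene Asns (-0.38) and Chac1 (-0.56). Leaving out 1 array at a time, Chac1 missed the threshold in 5 of 6 fits and Asns in 4. The list median was -0.16 (camera adjusted p = 0.000148; adjusted p = 0.131 with an estimated correlation). Of 20 p53 target genes 4 fell and 1 rose (5 and 1 adjusted over the list alone). The cell cycle inhibitor gene Cdkn1a (-0.74), the death receptor gene Fas (-0.66), Perp (-0.58) and the p53 ubiquitin ligase gene Mdm2 (-0.41) fell, and Mdm2 missed the threshold in 5 of the 6 fits that left out 1 array. That list was not called, and its median of 0.0017 differed in sign from its mean of -0.097 and its downward camera test (adjusted p = 0.277). BCL2 family and caspase genes had 3 rises and 3 falls among 17 (3 up and 5 down adjusted over the list alone; median -0.030, camera adjusted p = 0.368). The pro-death genes Bik (0.67) and Bmf (0.58) rose, and the caspase genes Casp4 (-0.97) and Casp6 (-0.77) fell. Of 25 interferon-stimulated genes 3 rose and 2 fell, also adjusted over the list alone (median 0.077, camera adjusted p = 0.368). Stat2 (0.95), Dhx58 (0.80) and Ifi35 (0.51) rose, and the antiviral gene Rsad2 (-0.64) fell, and Ifi35 missed the threshold in 2 of those 6 fits.

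Chemokines and chemoattractant receptors had 3 rises and 3 falls among 31 (5 and 4 adjusted over the list alone; median -0.037, camera adjusted p = 0.561). Ccr4, a receptor of type 2 lymphocytes, rose from 6.73 ± 0.16 to 7.97 ± 0.017, and the scavenging receptor gene Ackr3 rose by 1.47 on the log2 scale. Ccr1 fell from 8.32 ± 0.090 to 7.01 ± 0.14 and Cxcr6 from 8.28 ± 0.031 to 7.16 ± 0.083. TNF superfamily ligands and receptors had 3 rises and 3 falls among 24 (3 up and 5 down adjusted over the list alone; median -0.042, camera adjusted p = 0.561). Tnfrsf25, the receptor for TL1A, rose from 4.37 ± 0.40 to 5.84 ± 0.050 (limma adjusted p = 0.00222) and Tnfrsf26 from 6.17 ± 0.13 to 7.32 ± 0.068, while the ligand gene Tnfsf14 fell from 6.05 ± 0.16 to 5.02 ± 0.065 and Tnfsf10 fell as given above. Integrins and adhesion molecules also had 3 rises and 3 falls among 24 (3 up and 5 down adjusted over the list alone; median -0.053, camera adjusted p = 0.561). Itgb5 (0.75) and Itgb3 (0.59) rose, and Itgax (-1.04) and the selectin ligand gene Selplg (-0.57) fell.

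Camera called 11 of the 28 lists lower and 0 higher, and 0 lists were higher at an unadjusted p under 0.05. With an estimated correlation it called 0 lists in either direction, and 7 were lower at an unadjusted p under 0.05. Fry, which tests whether the genes of a list move one way on balance, called 10 lists lower and 0 higher. These were 9 of the 11, without S phase genes (adjusted p = 0.0779) and glycolysis (adjusted p = 0.05), together with the ILC2 identity list (adjusted p = 0.00146).

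**Figure D3:**
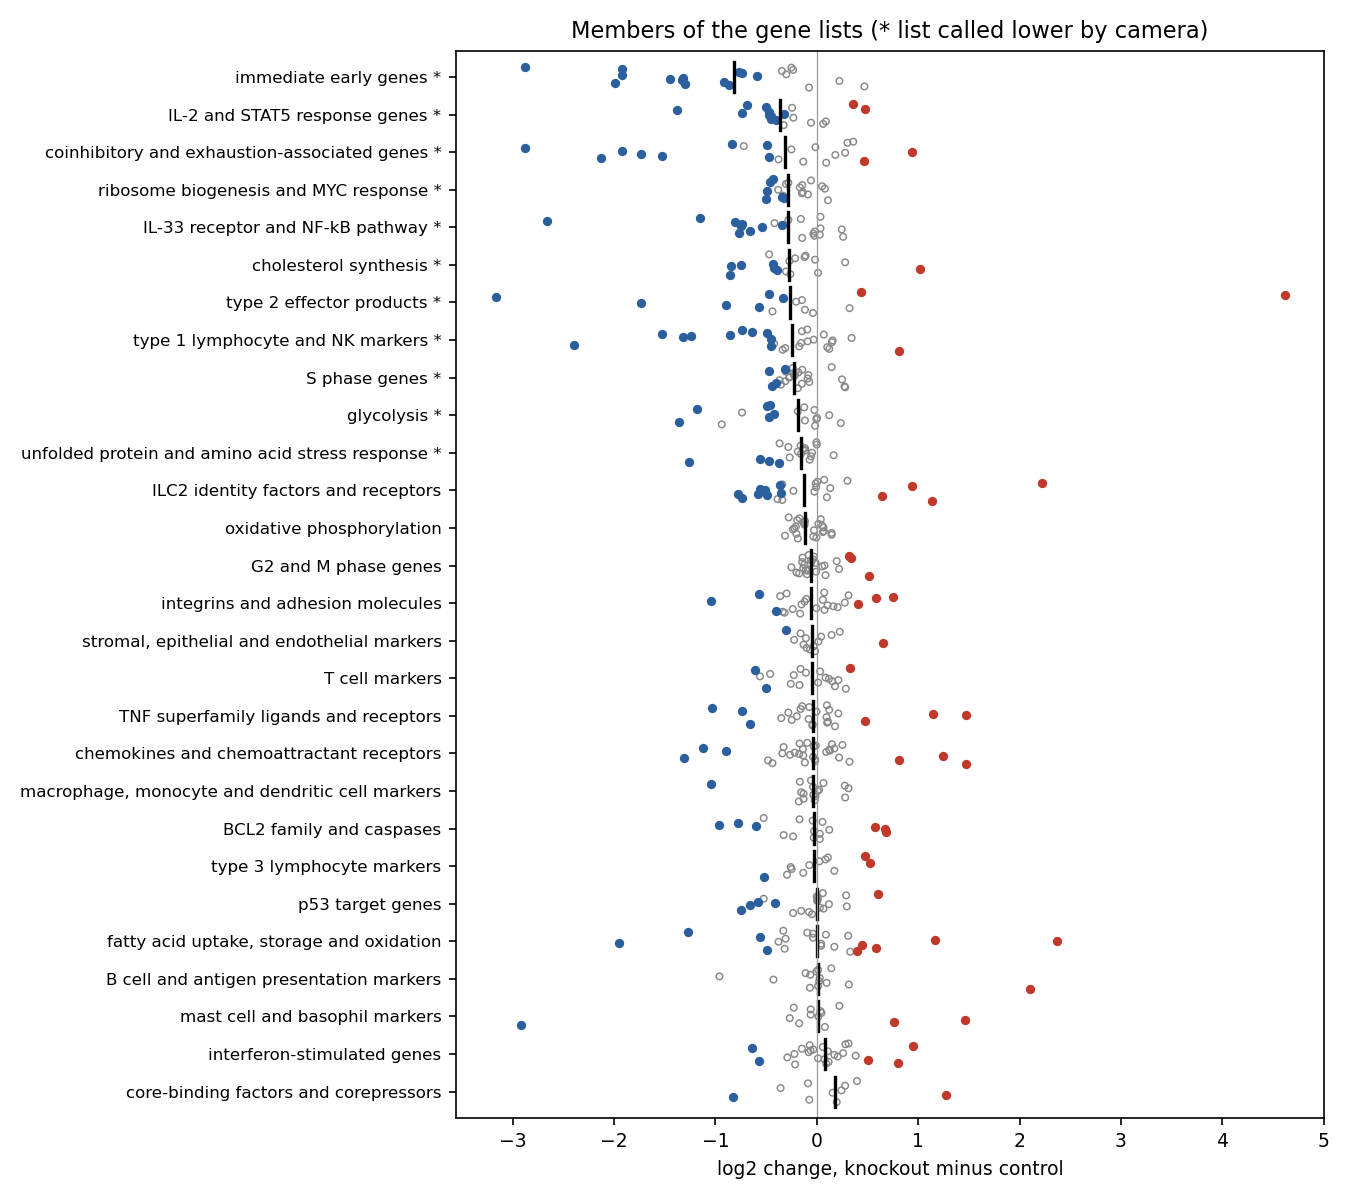
Log2 change (knockout minus control) of each measured member of the 28 gene lists, with blue and red points for members past the limma threshold, open points for the others and a black bar at the list median. Immediate early genes have the lowest median, at -0.82, and the core-binding factor list the highest, at 0.18.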

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

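Comparison with random lists matched on mean level was chosen after seeing the data. Cbfb fell past the limma threshold in all 13 alternatives computed for it (-0.89 to -0.76, adjusted p 3.89e-05 to 0.0318). Genes changed numbered 1254 with an ordinary test without moderation (genes higher 672, genes lower 582) and 280 with a change of at least 1 on the log2 scale (161 and 119). With a trended and robust prior 1626 genes were lower. Leaving out 1 array gave 1307 to 1837 genes changed (763 to 1113 higher, 544 to 786 lower). The low end came without control replicate 2. The counts were 1814 without control replicate 1, 1565 without control replicate 3, 1837 without knockout replicate 1, 1478 without knockout replicate 2 and 1517 without knockout replicate 3. These fits have fewer samples. The cause was not tested for the ordinary test and the trended prior, and the minimum change is a stricter criterion. In the gene fits other than the ordinary test, called genes shared with the reported ones had the same direction. Those fits use most or all of the same arrays, so this agreement is no independent support. Camera with an estimated correlation called 0 lists lower (estimates for the 11 reported lists from -0.03 for coinhibitory genes to 0.41 for S phase genes; the cause was not tested). The 11 reported lists stayed lower in each leave-out fit. Against matched random lists 1 list was higher, the core-binding factors (99.2th percentile), and 11 lower. The oxidative phosphorylation list became lower with array weights, which then gave 12 lists. Camera on ranks also called it (adjusted p = 0.0393) and not the coinhibitory list (adjusted p = 0.119), which gave 11.

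No pairing of the arrays by replicate number was seen in the values, which does not exclude one. Deviations of same-numbered arrays correlated at 0.025, 0.0067 and 0.054, and 1 of 3 control arrays correlated best with its own number. With the replicate number as a block the genes changed numbered 1745 (genes higher 1027, genes lower 718), 11 lists were lower and the same direction held for Cbfb (limma adjusted p = 0.0123). Of 151 genes followed by name, 1939 results under alternatives kept direction and side of the threshold in 1740, lost the call in 179, gained it in 15 and turned in 5. The gains were those of Il13, Pdcd1 and Lat in 3 alternatives each and of Il2ra, Batf and Cdk1 in 2 each, a trended prior and rows above the median level among them. Arg1 turned to 0.012 on repeated quantile normalisation, and over the leave-out fits it ran from -0.128 to 0.032, Klrg1 from -0.025 to 0.010 and Thy1 from -0.062 to 0.048; none of the 3 passed in the reported fit, and the cause was not tested. Of 129 genes followed and past the threshold, 101 passed in every leave-out fit, and Il5, Pecam1, Tyms, Ttk and Zap70 passed in none. Many of the 129 were named for a small adjusted p or a large change, so their share does not describe all changed rows. Of the 2457 changed rows, 1268 stayed called without control replicate 2, the fewest, and 1672 without knockout replicate 1, the most. The number of arrays and the absence of detection calls limit what can be said of dim genes.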

Other observations

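Genes in this paragraph were chosen after their values were seen. The zinc finger genes Egr1, Egr2 and Egr3, which are induced by receptor signalling, fell by 1.30, 1.99 and 0.92 on the log2 scale (limma adjusted p = 0.00115, 0.00116 and 0.00205; n = 3 arrays per group, no overlap). The Egr genes are members of the immediate early list and are already counted among its falls. Irf4, a transcription factor gene of activated lymphocytes, went from 9.66 ± 0.035 to 8.32 ± 0.13. The inhibitory receptor genes Havcr2 and Tigit, already counted among the falls of the coinhibitory list, fell by 1.53 and 0.84. The nucleotide receptor genes P2ry2 (7.10 ± 0.021 to 5.24 ± 0.049) and P2ry12 (5.91 ± 0.28 to 4.11 ± 0.086) fell as well. Among rises, Ebi3, which encodes a subunit of IL-27 and IL-35, went from 5.18 ± 0.17 to 7.03 ± 0.17. The protease inhibitor gene Slpi went from 8.89 ± 0.23 to 10.27 ± 0.015, Igfbp5, which encodes a binding protein of insulin-like growth factors, from 8.16 ± 0.16 to 9.70 ± 0.036, and Akr1c18 from 5.80 ± 0.12 to 7.46 ± 0.18.

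The tests of macrophage markers, of mast cell markers and of the remaining Cbfb transcript were chosen after their results were seen, and the lysosome, ERK feedback and Notch lists were drawn up after the gene table was seen and before they were tested. Gpnmb, Grn and Laptm4b, whose products reach lysosomes, rose, Laptm4b from 6.73 ± 0.040 to 8.15 ± 0.11. A rise across lysosomal genes may be the wider pattern. A list of 31 other lysosomal genes was higher by camera (limma adjusted p = 4.89e-08 over 3 lists, 1.63e-08 unadjusted; median 0.25), with 13 up and 2 down. With an estimated correlation the adjusted p was 0.263 (0.0878 unadjusted), and the call was lost; fry gave an adjusted p of 0.00165. The sulfatase gene Sgsh rose by 1.24 on the log2 scale, the cholesterol carrier gene Npc2 by 0.79, the galactosidase gene Glb1 by 0.76, the peptidase gene Tpp1 by 0.72 and the cathepsin gene Ctsz by 0.70 (limma adjusted p from 0.000314 to 0.00333). The lipase gene Lipa fell by 0.56 and the autophagy receptor gene Sqstm1 by 0.74, and Lipa missed the threshold in 5 of the 6 fits without 1 array.

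Camera called 11 of the 28 lists, all of them lower. Lower values of brightly expressed rows would leave the medians inside those of random lists of the same size and mean level, and 11 of 11 lay under the 2.5th percentile. A single deviating array is also argued against, since 11 lists passed in each of the 6 fits without 1 array. With an estimated correlation 0 lists passed. The estimate lay under the preset 0.01 for the coinhibitory (-0.03), type 1 (-0.0196), unfolded protein (-0.0179) and type 2 (0.00438) lists. Their unadjusted camera p still rose, to 0.0205, 0.00792, 0.0107 and 0.0414, so a higher correlation cannot account for that rise. For the other called lists shared variation of members between cultures stays open. An effect of the guide outside Cbfb and the timing of the cultures also stay open and were not tested. No biological explanation of this pattern was tested.

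Gpnmb and Fabp4, which macrophages also express, rose, and Cpa3, abundant in mast cells, fell. The GFP sort keeps transduced cells of any type, so macrophages in the knockout sort could account for the rises. Their other markers argue against this: among C1qa, C1qb, C1qc, Csf1r, Adgre1 and Mrc1 the highest upper 95% bound of a change was 0.62, with C1qa at 4.01 and 3.99 and Csf1r at 2.86 and 2.71 in control and knockout. Of the 17 macrophage markers 5 lay above the median level in control cells and 2 stand in another list. Fewer mast cells or basophils in the knockout sort would lower their other markers too. Of 13 measured, Cpa3 fell, 10 did not pass and 2, Hdc and Gata2, rose (Gata2 missed the threshold in 5 of the 6 fits without 1 array). Tpsb2, Cma1 and Mcpt8 read 2.44, 2.02 and 2.93 in control, too low for a fall to show. The markers therefore cannot tell fewer such cells from a change of expression within the ILC2s.

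The knockout arrays kept 56.4% of the Cbfb signal. If unedited cells with unaffected expression made up that share, no gene could fall below the level they keep. Yet 57 genes had a 95% interval wholly below the lower bound of the Cbfb change, -1.05, which argues against such cells as the whole source. This takes the array ratio of Cbfb as its share of transcript. An array can understate a fall, so the explanation is not excluded. Transcripts with a small deletion or insertion that are still made and read by the array may be a further source, and their share was not tested.

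The fall of Dusp5 (8.57 ± 0.24 to 6.66 ± 0.16), Ier3 and Fosl1 (7.45 ± 0.29 to 6.00 ± 0.16) raised the question of a fall across ERK feedback genes. A list of 11 others was not called (limma camera adjusted p = 0.338, 0.225 unadjusted; fry downward with adjusted p = 0.0527, 0.0351 unadjusted), with 2 down, Dusp6 (-0.38) and Phlda1 (-1.01), of which Dusp6 missed the threshold in 5 of the 6 fits without 1 array. The rise of Hey1 raised that of a rise across Notch response genes, and a list of 9 others was not called (limma camera upward with adjusted p = 0.578, fry adjusted p = 0.532; median -0.010, mean 0.075). In that list Hes1 alone rose, from 4.83 ± 0.23 to 5.62 ± 0.23, and it missed the threshold in 2 of those fits.

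The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2457 genes changed (1389 higher and 1068 lower), where the highest of the others gave 0, and 11 lists, where the highest of the others gave 4. In each case 1 of the 10 splits, the real one, gave as many. Every other split mixes arrays of both groups, so the group difference adds to its spread and makes gene calls less likely. Their counts therefore do not show what arrays without a group difference would give.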
